A study of Mus musculus with 12 samples.

How the data were processed

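RNA was sequenced from brown adipose tissue (BAT) and subcutaneous white adipose tissue (sWAT) of mice kept at 4 °C (cold) or at 30 °C (thermoneutral, the temperature at which a mouse needs no extra heat) for 72 hours. The labels give 20 male C57Bl/6 mice aged 8 to 12 weeks, 10 at each temperature. The series holds 12 libraries in 4 groups, with 3 libraries in each group. They were prepared from 1000 ng of total RNA with an Illumina TruSeq protocol for total RNA, read as pairs of 100 nt. Nothing in the labels says whether the 3 libraries of a group came from separate animals or from pools, or whether BAT and sWAT libraries with the same number came from the same animals. Each library has an experiment number, 1 to 3, that recurs in every group, and its meaning is not given. The p-values therefore measure the spread between these samples.

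The deposited table gives raw counts per gene, whole numbers without normalization, for 23163 gene symbols in the 12 libraries, and 0 of its columns were left without a sample. Per the labels, the authors used STAR and DESeq2 with the mm10 genome build, and no versions are stated. The counting tool, the strand setting, the annotation and any filter are not given in the sources used here. Genes that overlap on opposite strands, and near-identical paralogs such as Hspa1a and Hspa1b, are therefore uncertain as to which gene a read came from. The column names of BAT cold library 1 and sWAT cold library 2 begin with the word Merged, and no source says what was merged. Both were used as they stand.

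Totals ranged from 27117934 to 56243016 counts per library. Shares of counts taken by the 13 mitochondrially encoded genes and by 109 ribosomal protein genes were computed per library with Wilson 95% confidence intervals, which were at most 0.0345 percentage points wide. Such intervals cover counting error only. Pairs of libraries were compared for duplicate columns, and none were duplicates.

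Groups were compared in R 4.3.3 with edgeR 4.0.16 (limma 3.58.1). Genes were kept by filterByExpr, totals were scaled by TMM factors, and edgeR's quasi-likelihood test (glmQLFit with robust=TRUE, glmQLFTest) was applied. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05 and no minimum fold. There were 5 comparisons. Cold was compared with thermoneutral in the 6 BAT libraries and in the 6 sWAT libraries, each tissue with its own spread. A fit over all 12 libraries with 4 group means compared the response to cold between sWAT and BAT, and compared BAT with sWAT at thermoneutrality and in cold. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Printed CPM are scaled by the total times the TMM factor over 12 libraries, as mean ± SD of the 3 libraries of a group. Overlap of the responses in BAT and sWAT was tested with Fisher's exact test, one-sided, among genes tested in both.

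A total of 34 gene lists, covering metabolic pathways, stress responses, regulators and markers of other cell types, were tested as sets with camera at a preset correlation of 0.01, adjusted over the lists with at least 5 measured members. The same tests were run with a correlation estimated from the data. Each list was also counted gene by gene, with p-values adjusted over all genes and adjusted over the list alone. fry, which asks whether a list's genes move on balance in one direction without comparing them with other genes, was run beside them.

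The named genes follow a rule. It takes 11 genes in every comparison (Ucp1, Dio2, Ppargc1a, Cidea, Elovl3, Fgf21, Lep, Adipoq, Fasn, Cirbp and Rbm3). It adds the 5 genes with the largest positive and the 5 with the largest negative log2 fold change, or 3 and 3 where tissues are compared, past adjusted p 0.05 with a mean log2 CPM of at least 3, no overlap between the groups and no symbol of a predicted gene model. The overlap condition was left out for the difference of responses. From each list it takes up to 4 members past the threshold with the smallest adjusted p, or up to 2 where none passed. Some genes that the rule takes are not reported here. The groups, comparisons, tests, lists, rule for named genes and most alternatives were fixed before the data were examined.

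GC content, positions and gene identifiers came from GENCODE M21, matched by symbol, with the longest transcript of each gene. A GC value was found for 22240 genes, 96.0% of the table, and for at least 96.6% of the members of each list. Library composition was described by a principal component analysis of log2 CPM with a prior count of 2, by Spearman correlations between libraries, and by the slope of log2 CPM on GC content.

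Alternatives changed one choice at a time. They were median-of-ratios (RLE) and upper quartile scaling, totals without the 10 genes with the highest CPM, no filter, a filter of 1 CPM in 3 libraries, robust=FALSE, the DESeq2 1.42.0 Wald test, limma-voom, a minimum log2 fold change of 1, counts thinned to the smallest total with seed 1, a block for the library number, another choice of libraries in the fit, and leaving out each library in turn. Further alternatives were chosen after seeing the data. They were the removal of a loess trend (span 0.5) of log2 CPM on GC content from each library, totals without the 13 mitochondrial genes, the fit without both BAT libraries numbered 3, and the fit without these and sWAT cold library 1. Values under the loess correction are called GC-corrected.

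The tests were run on simulated data with 58 to 70 genes changed per size. In BAT, 8.57%, 70.7% and 90.0% of genes changed by a log2 of 1, 2 and 3 were recovered, and in sWAT 8.70%, 75.4% and 97.0%. For the difference of responses the shares were 0%, 31.1% and 69.6%, for BAT against sWAT at thermoneutrality 1.43%, 70.5% and 94.2%, and in cold 4.29%, 63.9% and 94.2%. False calls made up 5.17%, 5.69%, 10.7%, 6.03% and 1.83% of the calls. With a simulated GC trend of 1.5 log2 per 10 percentage points between groups of otherwise equal samples, 4965 of 15731 genes were called without the GC correction and 0 with it. Among 33 simulated lists, camera called 1, the raised one, leaving correlation in real lists untested.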

Results

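The data are RNA sequencing counts from BAT and sWAT of mice kept for 72 hours at 4 °C or at 30 °C, with 3 libraries for each tissue and temperature. Total counts were 29568610, 42616691 and 56243016 in BAT cold libraries 1, 2 and 3, and 29253388, 42148940 and 36837936 in BAT thermoneutral libraries 1, 2 and 3. In sWAT they were 53485998, 36837744 and 33695611 in cold libraries 1, 2 and 3, and 29404276, 27117934 and 29172972 in thermoneutral libraries 1, 2 and 3. Below, a log2 fold change is given as value ± SE from 3 libraries per group, and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. For gene lists they are from camera.

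The sWAT thermoneutral libraries stood apart in composition. Genes encoded in mitochondrial DNA took 0.181%, 0.307% and 0.231% of their counts, against 33.6%, 19.7% and 23.4% in sWAT cold libraries 1, 2 and 3. In BAT the shares were 24.4%, 20.0% and 53.8% in cold and 34.8%, 37.7% and 17.6% at thermoneutrality. Ribosomal protein genes took 6.43%, 7.19% and 6.39% in sWAT thermoneutral libraries, and 0.323% to 1.64% in the other 9 libraries. The slope of log2 CPM on GC content was 1.21, 0.95 and 0.64 per 10 percentage points in sWAT thermoneutral libraries. It was −0.62, 0.02 and −0.26 in sWAT cold, 0.01, 0.09 and −0.89 in BAT cold, and −0.24, −0.33 and −0.58 in BAT thermoneutral libraries. On the first principal component, with 62.8% of the variance, the 3 sWAT thermoneutral libraries scored 169 to 178 and the others at most 21.6. The libraries numbered 3 in both BAT groups and sWAT cold library 1 had the lowest slope of their groups, and BAT cold library 3 had the highest mitochondrial share of the 12.

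Markers of other cell types also varied. B and T lymphocyte markers averaged 1.00 to 1.65 CPM in the 6 BAT libraries, 86.4, 28.6 and 24.2 CPM in sWAT cold and 100.1, 74.3 and 107.2 CPM in sWAT thermoneutral libraries. Skeletal muscle markers averaged 483, 1218 and 1237 CPM in sWAT cold and 109, 270 and 8.07 CPM in sWAT thermoneutral libraries. In BAT they averaged 318, 416 and 298 CPM in cold and 225, 676 and 791 CPM at thermoneutrality. Spearman correlations across genes, which are not independent replicates, were 0.942 to 0.994 between libraries of a group. They were 0.924 to 0.960 between BAT cold and BAT thermoneutral libraries, and 0.827 to 0.859 between sWAT cold and sWAT thermoneutral libraries.

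**Figure D1:**
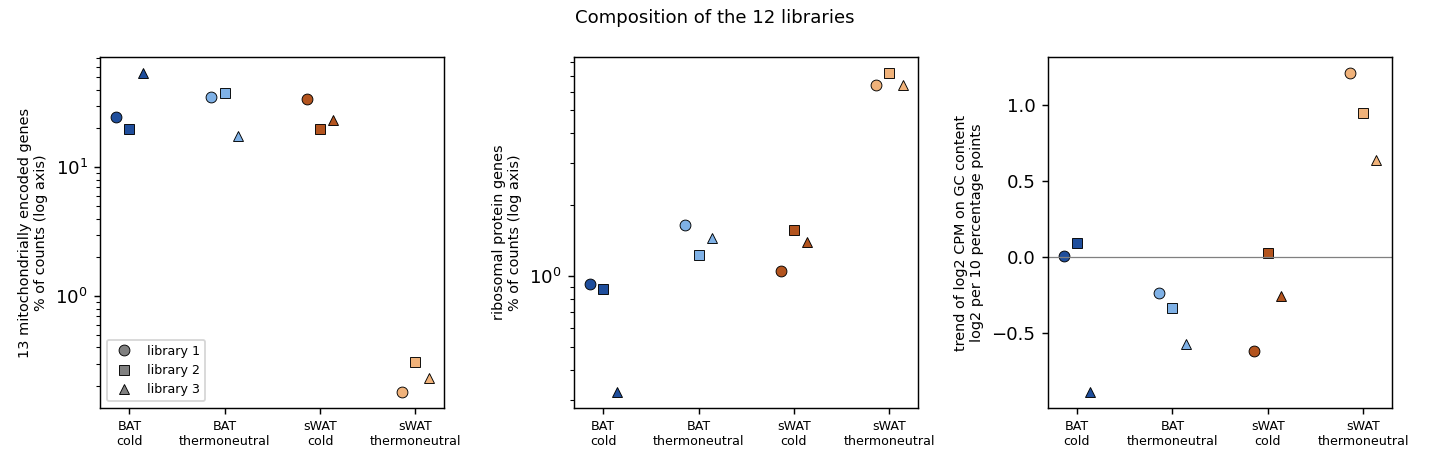
Share of counts from mitochondrial genes and from ribosomal protein genes (both in percent, log axes) and slope of log2 CPM on GC content (log2 per 10 percentage points) in each of the 12 libraries, where circle, square and triangle are libraries 1, 2 and 3 of a group. The 3 sWAT thermoneutral libraries sit at 0.181% to 0.307% mitochondrial counts.

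Cold against thermoneutral BAT shows how the tissue whose main task is heat production responds to cold. Ucp1 (ENSMUSG00000031710.4, mm10 chromosome 8, 83290352 to 83298452) encodes the protein that lets mitochondria release energy as heat. It rose from 1929 ± 575 to 21898 ± 1603 CPM (SD, n = 3), a log2 fold change of 3.56 ± 0.38 (adjusted p = 0.00190). Elovl3 (ENSMUSG00000038754.5, chromosome 19, 46131897 to 46135694), an elongase of very long fatty acids, rose from 8.37 ± 1.89 to 1103 ± 56.4 CPM (7.10 ± 0.36, adjusted p = 0.000143). Lep (ENSMUSG00000059201.12, chromosome 6, 29060220 to 29073877), which encodes the hormone leptin, fell from 67.9 ± 2.98 to 10.8 ± 3.71 CPM (−2.60 ± 0.32, adjusted p = 0.00314). Dio2 (ENSMUSG00000007682.6, chromosome 12, 90724552 to 90738438), which activates thyroid hormone, rose by 1.89 ± 0.42 (adjusted p = 0.0241). Ppargc1a (ENSMUSG00000029167.13, chromosome 5, 51454250 to 51567726), a coactivator that drives mitochondrial biogenesis, rose by 2.43 ± 0.51 (adjusted p = 0.0202). Bmp8b, a signal secreted by brown fat, rose to 32.4 ± 6.99 CPM from 0.0199 ± 0.0184 CPM, close to 0 counts.

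Among genes with a mean log2 CPM of at least 3, the largest increases in BAT besides Elovl3 were those of Slc25a34, a mitochondrial carrier (5.74 ± 0.45), Dhrs9, a retinol dehydrogenase (4.54 ± 0.60), the sorting receptor Sorl1 (4.29 ± 0.32) and Loxl1, which crosslinks elastin (4.22 ± 0.66). The largest decreases among such genes were those of Lctl (−4.76 ± 0.37), the stress-induced chaperones Hspa1b (−4.52 ± 0.96) and Hspa1a (−4.27 ± 0.84), the cadherin Cdh23 (−3.08 ± 0.35) and the glutamate receptor gene Grik5 (−2.94 ± 0.36). Fasn, the fatty acid synthase, rose by 1.94 ± 0.40 (adjusted p = 0.0179). Fgf21, a hormone that fat can release, rose from 0.145 ± 0.170 to 2.35 ± 1.25 CPM (adjusted p = 0.0182), and had 0.0556, 0.0619 and 0.0835 without cold library 1, cold library 2 or thermoneutral library 1 (5.82e-06 to 0.0835 over all alternatives). Others named in every comparison did not pass in BAT. Cidea, a lipid droplet protein of brown fat, had a log2 fold change of 0.16 ± 0.29 (adjusted p = 0.753), Adipoq, which encodes adiponectin, −1.38 ± 0.43 (0.0724), and the cold-inducible RNA-binding genes Cirbp −0.89 ± 0.32 (0.101) and Rbm3 −1.46 ± 0.43 (0.0626). Single libraries decided some of these calls. Without BAT cold library 2, thermoneutral library 1 or thermoneutral library 2, Dio2 had an adjusted p of 0.0709, 0.0867 and 0.0991 (0.000194 to 0.0991). Ppargc1a had 0.0741, 0.0684 and 0.0938 under the same conditions (2.49e-05 to 0.0938). Without cold library 1, cold library 2, thermoneutral library 1 or thermoneutral library 2, Fasn had 0.0802, 0.0935, 0.0709 and 0.0634 (2.15e-06 to 0.0935). Without cold library 1, thermoneutral library 1 or thermoneutral library 2, Hspa1b had 0.0672, 0.0730 and 0.0708 (2.58e-06 to 0.0730), and Hspa1a 0.0544, 0.0610 and 0.0607 (3.32e-08 to 0.0610). Loxl1 had 0.0506 without thermoneutral library 2 (9.14e-12 to 0.0506), and Rbm3 passed without cold library 3 (−1.89, adjusted p = 0.0285; 0.000174 to 0.198). Adipoq (−1.30, 0.0415; 0.0193 to 0.194), Cirbp (−1.03, 0.0197; 0.0197 to 0.211) and Rbm3 (−1.37, 0.0176) passed with the GC correction.

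Genes of heat production and lipid metabolism rose together in BAT. Of 27 genes of the thermogenic programme, 13 rose and the other 14 did not pass (16 rose and 1 fell when adjusted over the list alone), with a median log2 fold change of 1.20. Acot11, an acyl-CoA thioesterase, rose by 3.78 ± 0.31 and the nuclear receptor Esrrb by 4.04 ± 0.41 (list adjusted p = 5.72e-13, and adjusted p = 0.135 with an estimated correlation). In de novo lipogenesis 10 of 21 rose (12 adjusted over the list alone), among them Acly, which makes cytosolic acetyl-CoA (2.71 ± 0.32), and Scd2, a desaturase (2.17 ± 0.27); the median was 1.22 (adjusted p = 1.57e-06, and adjusted p = 0.177 with an estimated correlation). Of 22 genes of cholesterol synthesis, 10 rose, 1 fell and 11 did not pass (13 and 1 adjusted over the list alone). Sqle (2.49 ± 0.28) and Sc5d (2.00 ± 0.30) were among those that rose, with a list median of 0.98 (adjusted p = 8.54e-08, and adjusted p = 0.123 with an estimated correlation). Of 26 genes of fatty acid oxidation, 9 rose and 17 did not pass (11 rose adjusted over the list alone). Acsl5, which activates fatty acids, rose by 3.68 ± 0.39 and Hadha, of the mitochondrial oxidation spiral, by 1.97 ± 0.30 (median 0.69, adjusted p = 5.60e-06, and adjusted p = 0.177 with an estimated correlation).

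Of 28 genes of lipolysis and lipid uptake, 9 rose and 19 did not pass (13 rose and 1 fell adjusted over the list alone). Gpd1 (2.90 ± 0.35) and the glycerol kinase gene Gk (3.35 ± 0.42) were among them, and the list median was 0.92 (adjusted p = 5.15e-07, and adjusted p = 0.217 with an estimated correlation). In glucose uptake and glycolysis 12 of 30 rose and 1 fell (14 and 1 adjusted over the list alone), with Pfkp at 2.68 ± 0.27 and Hk1, a hexokinase, at 2.50 ± 0.30 (median 1.00, adjusted p = 4.11e-07, and adjusted p = 0.217 with an estimated correlation). Of 20 genes of the citric acid cycle, 3 rose and 17 did not pass (5 rose adjusted over the list alone), with a median of 0.71 (adjusted p = 0.00103, and adjusted p = 0.517 with an estimated correlation). Ogdh, of the oxoglutarate dehydrogenase complex, rose by 2.00 ± 0.34, with an adjusted p of 0.0518 without BAT cold library 2 (5.16e-08 to 0.0518 over all alternatives). Of 18 secreted factors of thermogenic fat, 4 rose and 14 did not pass (5 rose and 2 fell adjusted over the list alone). Npr3, the natriuretic peptide clearance receptor of that list, rose by 2.33 ± 0.31 (median 0.52, adjusted p = 0.00103, and adjusted p = 0.135 with an estimated correlation).

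Subunits of the mitochondrial respiratory chain were not called in BAT. Of 55 nuclear genes of the respiratory chain, 0 passed in edgeR, 7 had an unadjusted p under 0.05, 4 passed in DESeq2 and 0 in limma-voom. Their median was 0.02, their mean 0.00, and the direction of the test was down (adjusted p = 0.864). Of the 13 genes encoded in mitochondrial DNA, 0 passed in edgeR, 3 had an unadjusted p under 0.05, 3 passed in DESeq2 and 0 in limma-voom. Their list median was 0.98 (adjusted p = 0.0545), and the mitochondrial share of counts ran from 17.6% to 53.8% within the 6 BAT libraries. This list passed without BAT cold library 1, cold library 2, thermoneutral library 1 or thermoneutral library 2, with adjusted p of 0.00302, 0.000823, 0.0292 and 0.00700, and with the GC correction (0.00742), within 0.000823 to 0.726 over all alternatives. Without cold library 3 the median was 0.17 (adjusted p = 0.449), and without thermoneutral library 3 it was 0.49 (0.393).

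The list of immediate early genes, which respond within minutes to stimulation, was called lower in cold BAT at the preset correlation. Of 17, 10 fell and 7 did not pass (11 fell adjusted over the list alone), with a median of −1.69 (adjusted p = 7.60e-08, and adjusted p = 0.123 with an estimated correlation). Nr4a3 fell by 2.54 ± 0.31, Fosb by 3.10 ± 0.46 and Egr2 by 2.77 ± 0.42. Of 8 erythrocyte markers, 2 rose and 6 did not pass (3 rose adjusted over the list alone), with a median of 1.48 (adjusted p = 0.00321, and adjusted p = 0.511 with an estimated correlation). Of 30 extracellular matrix genes, 6 rose, 1 fell and 23 did not pass (7 and 1 adjusted over the list alone), with a median of 0.43 (adjusted p = 0.0404, and adjusted p = 0.726 with an estimated correlation). The matrix call was lost without BAT cold library 3 (adjusted p = 0.315), thermoneutral library 2 (0.101) or thermoneutral library 3 (0.107), and with the GC correction (0.0625), within a range of 0.00171 to 0.726 over all alternatives. Splicing regulators, named in the series title, were not called as a list. Of 107 measured, 4 rose, 3 fell and 100 did not pass (4 and 1 adjusted over the list alone), with a median of −0.19 (adjusted p = 0.373), and 8 rose and 11 fell with the GC correction. The neuronal RNA-binding gene Elavl3 rose by 2.61 ± 0.32.

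For the other lists in BAT the counts adjusted over the list alone are given where they differ. Of 14 genes of creatine and calcium cycling 3 rose (4 rose and 2 fell adjusted over the list alone; median 0.19, adjusted p = 0.0885), with Atp2a2, a calcium pump, at 1.73 ± 0.26. Of 19 clock genes 4 rose and 2 fell (4 and 4 adjusted over the list alone), with Arntl at 2.92 ± 0.37; the median was −0.07, the mean 0.21 and the direction of the test up (adjusted p = 0.657). Of 16 heat shock genes 4 rose, such as Hspa4l (2.05 ± 0.33), and 2 fell (7 and 2 adjusted over the list alone; median 0.71, adjusted p = 0.143). Of 19 white adipocyte genes 1 rose and 2 fell, among them Nnat (−2.39 ± 0.40); the median was 0.34, the mean 0.03 and the direction of the test down (adjusted p = 0.869). Of 14 beige and brown lineage markers 1 rose (median 0.33, adjusted p = 0.528), and of 7 cold-inducible RNA-binding genes 1 fell (3 adjusted over the list alone; −0.75, 0.253). In the unfolded protein response 2 of 24 rose and 1 fell (3 and 3 adjusted over the list alone; 0.17, 0.412), and in the cell cycle 2 of 26 rose (1 adjusted over the list alone; 0.34, 0.391).

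Among lists of other cell types in BAT, 1 of 17 lymphocyte markers fell (5, and 1 rose, adjusted over the list alone; median −0.56, adjusted p = 0.0782), 3 of 24 skeletal muscle markers fell (−0.85, 0.156), 1 of 15 endothelial markers rose (0.11, 0.528), and 1 of 7 lymphatic markers fell (−0.03, 0.596). In fibroblast markers 1 of 14 rose and did not pass adjusted over the list alone (0.21, 0.414), and in Schwann and nerve markers 1 of 10 rose (−0.55, 0.412). In 5 lists 0 genes passed in edgeR. They were macrophage markers (19 genes, 2 with an unadjusted p under 0.05, 1 past DESeq2 and 1 past limma-voom; median −0.28, adjusted p = 0.253), neutrophil and mast cell markers (8 genes, 1, 0 and 0; 0.08, 0.547), and smooth muscle and pericyte markers (10 genes, 2, 1 and 0; 0.24, 0.393). The eosinophil markers (3 genes, 1, 0 and 0, and 1 lower adjusted over the list alone) and thymus markers (1 gene, 0, 0 and 0) had too few members for a list test, as had the epithelial markers (2 genes, of which 1 fell). The lymphocyte list passed without thermoneutral library 2 (adjusted p = 0.0141, 0.0141 to 0.726 over all alternatives). Muscle markers passed without thermoneutral library 1 (5.96e-06, to 0.829), neutrophil markers without thermoneutral library 3 (0.00688, to 0.876), and creatine and calcium cycling without cold library 1 or thermoneutral library 2 (0.0463 and 0.0442, 0.0353 to 0.325).

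In BAT 1777 of 14612 genes passed, 996 higher and 781 lower in cold, and 938 and 758 of these changed at least 2-fold. The counts depended on single libraries. They were 362 and 167 without cold library 1, 305 and 146 without cold library 2, 338 and 250 without thermoneutral library 1, and 303 and 200 without thermoneutral library 2. Without both BAT libraries numbered 3, chosen after seeing the data, they were 3265 and 3244, and with the GC correction 1576 and 1521. With upper quartile scaling 41.5% of the genes that passed were higher in cold, against 56.0% in the main test, and the median log2 fold change of all genes moved from −0.04 to −0.20. Camera called 11 of 31 lists, and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05; fry called 12.

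**Figure D2:**
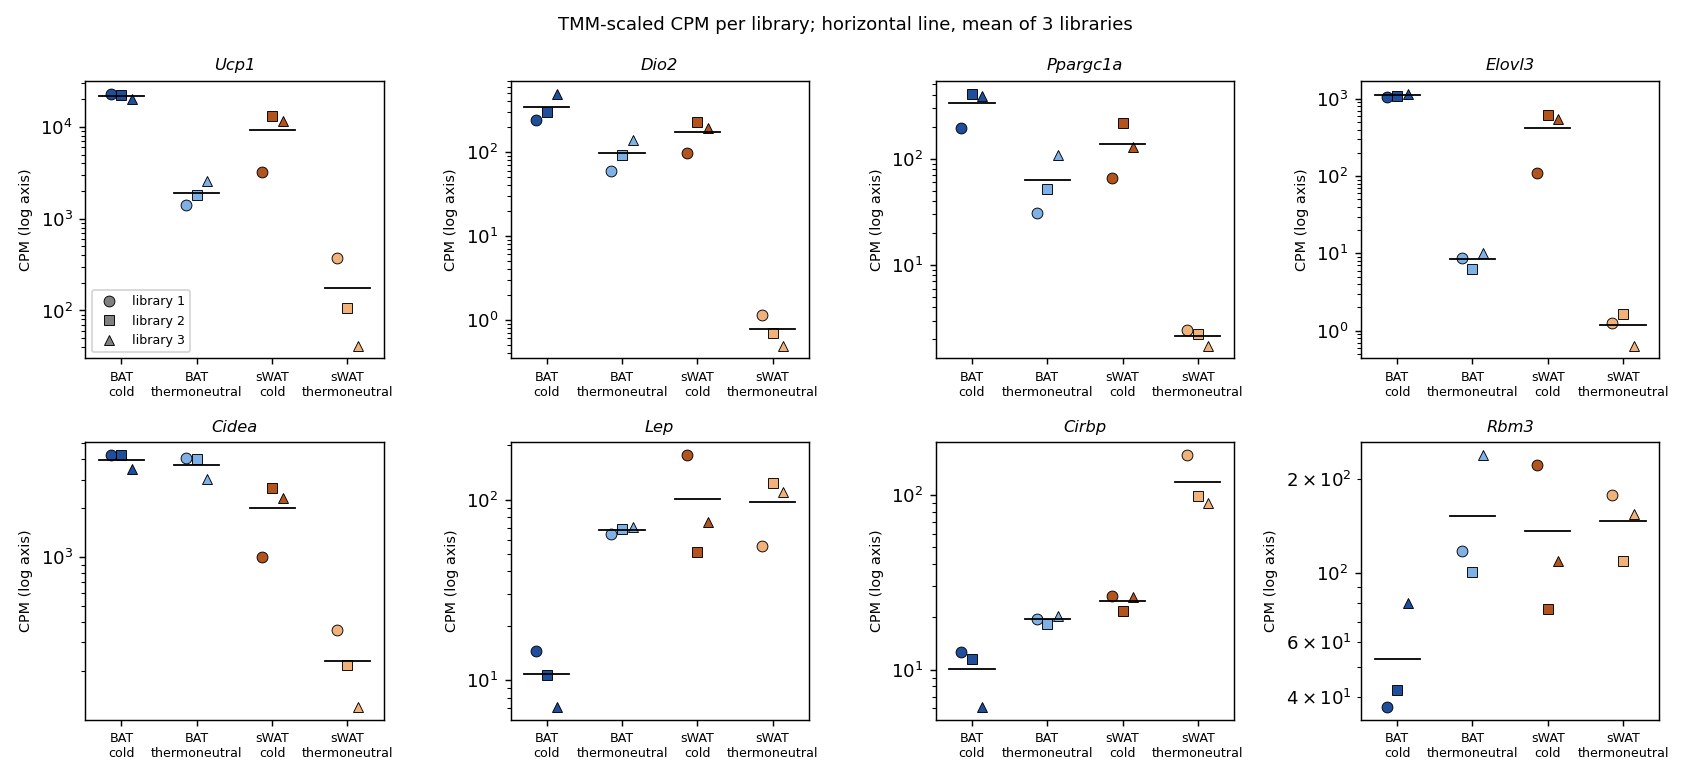
CPM (log axis, TMM-scaled) of Ucp1, Dio2, Ppargc1a, Elovl3, Cidea, Lep, Cirbp and Rbm3 in each of the 12 libraries by tissue and temperature, with a line at the mean of 3 libraries. Mean Ucp1 was 21898 CPM in BAT cold, 1929 in BAT thermoneutral, 9342 in sWAT cold and 175 in sWAT thermoneutral libraries.

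Cold sWAT, a fat depot that stores lipid and can turn on heat production, was compared with thermoneutral sWAT. A batch of the 3 thermoneutral libraries, which stood apart in composition, cannot be told apart from the temperature. Ucp1 rose from 175 ± 178 to 9342 ± 5370 CPM (SD, n = 3), a log2 fold change of 5.72 ± 0.98 (adjusted p = 0.00203), and was 3211, 13212 and 11603 CPM in cold libraries 1, 2 and 3, and 377, 106 and 41.2 CPM in thermoneutral ones (its fold moves by over 1.5 times without thermoneutral library 1). Dio2 rose from 0.779 ± 0.330 to 173 ± 68.0 CPM (7.79 ± 0.52, adjusted p = 0.000174), Elovl3 by 8.47 ± 0.81 (0.000264), Ppargc1a by 5.98 ± 0.48 (0.000198) and Cidea by 3.09 ± 0.55 (0.00230). Cirbp (ENSMUSG00000045193.13, chromosome 10, 80165985 to 80172786) fell from 119 ± 43.3 to 24.5 ± 2.63 CPM (−2.28 ± 0.31, adjusted p = 0.000835). Fgf21 rose from 0.127 ± 0.110 to 1.98 ± 1.43 CPM (adjusted p = 0.00738). Lep had 101 ± 66.6 CPM in cold and 96.9 ± 36.4 at thermoneutrality, a log2 fold change of 0.07 ± 0.49 (adjusted p = 0.910), and Adipoq −0.30 ± 0.32 (0.447). Fasn had 1.08 ± 0.58 (adjusted p = 0.151) and passed with the GC correction (2.04, 0.0116) and without thermoneutral library 1 (1.84, 0.0386), within 0.0116 to 0.349 over all alternatives. Rbm3 had −0.10 ± 0.42 (adjusted p = 0.854) and passed with the GC correction (−1.34, 0.0241; 0.0241 to 0.947).

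Changes in sWAT followed the GC content of the genes. In nuclear genes under 40% GC the median log2 fold change was 1.60, and in those of at least 60% it was −1.19. Across genes, which are not independent replicates, the Spearman correlation of fold change and GC content was −0.51, against 0.11 in BAT. GC-corrected log2 fold changes were 5.45 for Ucp1, 6.98 for Dio2, 8.52 for Elovl3, 4.95 for Ppargc1a, 3.82 for Cidea and −1.73 for Cirbp. GC-corrected list medians were 1.11 for the nuclear respiratory chain, 2.08 for the citric acid cycle, 1.73 for fatty acid oxidation, 1.40 for lipolysis and lipid uptake, 1.85 for glycolysis, 1.65 for de novo lipogenesis and 1.34 for cholesterol synthesis. They were 2.41 for creatine and calcium cycling, 1.73 for heat shock genes, 4.46 for muscle markers, −1.09 for macrophage, −1.30 for lymphocyte and −1.36 for neutrophil and mast cell markers, and −1.05 for the cell cycle.

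**Figure D3:**
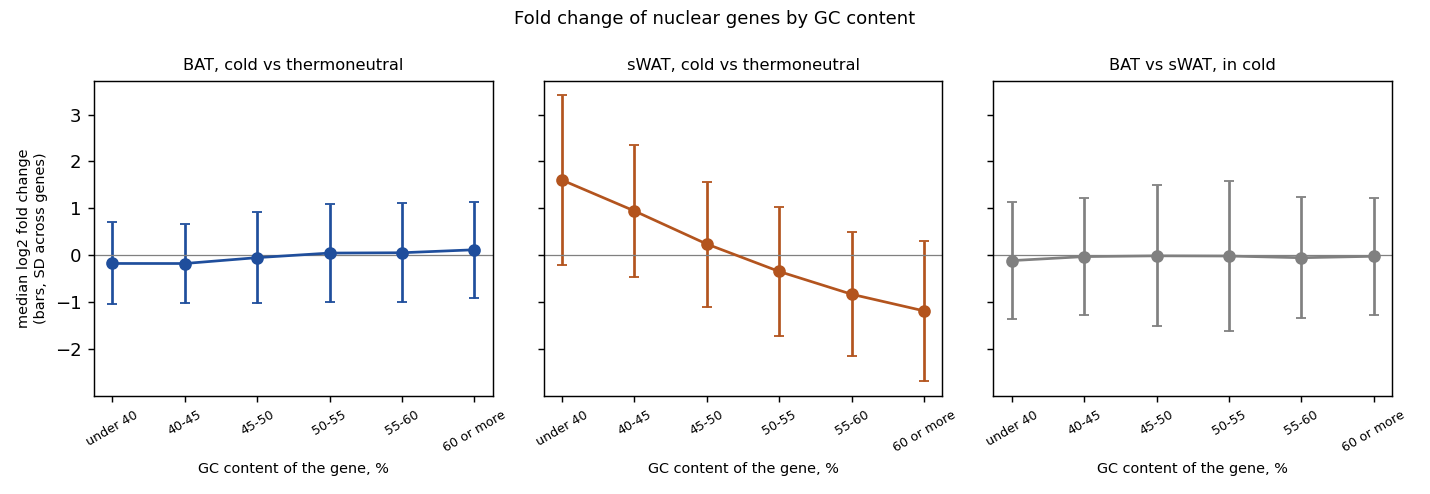
Median log2 fold change of nuclear genes by GC content of the gene (percent, in bins), with bars of 1 SD across genes, for cold against thermoneutral BAT, cold against thermoneutral sWAT, and BAT against sWAT in cold. The medians run from 1.60 under 40% GC to −1.19 at 60% and above in sWAT, and from −0.18 to 0.11 in BAT.

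In sWAT, where 49.2% of all genes tested passed, counts adjusted over the list alone are given where they differ. Of the lists tested, the mitochondrial genes had the largest median. All 13 passed, with a median of 7.80 (adjusted p = 1.70e-30, 0.314 with an estimated correlation) and of 5.73 with the GC correction. The largest of the list were mt-Nd1 (8.44 ± 0.67, GC-corrected 6.69) and mt-Nd2 (8.23 ± 0.58, GC-corrected 6.19), subunits of complex I, mt-Nd6 (7.99 ± 0.56, 5.65) and mt-Atp6 (7.90 ± 0.64, 5.84). Of 55 nuclear respiratory chain genes, 23 rose, 1 fell and 31 did not pass (22 and 1 adjusted over the list alone), with Uqcrb at 7.29 ± 0.41, Uqcrc2 at 3.47 ± 0.35 and Cycs, cytochrome c, at 5.09 ± 0.75 (median 0.97, adjusted p = 0.00299, 0.759 with an estimated correlation). Of 20 genes of the citric acid cycle, 17 rose and 3 did not pass (18 rose adjusted over the list alone), with Dld at 4.72 ± 0.38 and Sucla2 at 4.34 ± 0.46 (median 2.11, adjusted p = 8.59e-07, 0.700 with an estimated correlation). Muscle is rich in genes of respiration, the citric acid cycle and calcium cycling, and its markers rose too (483 to 1237 CPM in cold, 8.07 to 270 at thermoneutrality), so the share of muscle in the samples is not told apart from a change in adipocytes.

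Of 27 thermogenic genes in sWAT, 21 rose, 1 fell and 5 did not pass (22 and 1 adjusted over the list alone), with a median of 3.36 and GC-corrected of 3.57 (adjusted p = 1.70e-08, and adjusted p = 0.700 with an estimated correlation). Esrrg, a nuclear receptor of oxidative tissue, rose by 4.50 ± 0.33. Of 26 genes of fatty acid oxidation, 18 rose, 1 fell and 7 did not pass, with Decr1 at 3.51 ± 0.32 and Etfdh at 3.23 ± 0.37 (median 1.69, adjusted p = 3.59e-05, and adjusted p = 0.700 with an estimated correlation). In lipolysis and lipid uptake 14 of 28 rose and 1 fell, with Gk at 5.66 ± 0.47 and the lipoprotein receptor gene Vldlr at 3.44 ± 0.28 (median 0.84, adjusted p = 2.26e-04, and adjusted p = 0.700 with an estimated correlation). In glucose uptake and glycolysis 19 of 30 rose and 2 fell (21 and 2 adjusted over the list alone). Gys2, a glycogen synthase, rose by 3.64 ± 0.24 and Eno2 fell by 2.39 ± 0.37 (median 1.56, adjusted p = 1.68e-04, and adjusted p = 0.700 with an estimated correlation). In de novo lipogenesis 12 of 21 rose, with Elovl6 at 4.02 ± 0.37 (median 1.24, adjusted p = 0.00385, and adjusted p = 0.700 with an estimated correlation). Of 22 genes of cholesterol synthesis 12 rose (12 rose and 1 fell adjusted over the list alone), with Nsdhl at 3.52 ± 0.29 and Idi1 at 3.23 ± 0.29 (median 1.14, adjusted p = 2.54e-04, and adjusted p = 0.636 with an estimated correlation). Of 14 genes of creatine and calcium cycling 9 rose and 2 fell, with Sln, a regulator of the calcium pump that is also expressed in muscle, at 6.02 ± 0.83 (median 1.84, adjusted p = 0.0206, and adjusted p = 0.703 with an estimated correlation). Of 16 heat shock genes 11 rose, with the mitochondrial chaperone gene Hspd1 at 3.15 ± 0.34 (median 1.57, adjusted p = 4.98e-04, and adjusted p = 0.700 with an estimated correlation).

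Several immune and cell cycle markers fell in cold sWAT, with cell shares not told apart from a response. Of 19 macrophage markers, 10 fell, 2 rose and 7 did not pass, with the complement genes C1qa at −2.72 ± 0.28 and C1qb at −2.06 ± 0.23 (median −1.35, adjusted p = 0.00278, and adjusted p = 0.700 with an estimated correlation). Of 20 lymphocyte markers 10 fell (10 fell and 1 rose adjusted over the list alone), with the T cell kinase gene Lck at −2.49 ± 0.36 and the B cell receptor gene Cd79b at −2.01 ± 0.35 (median −1.28, adjusted p = 0.00397, and adjusted p = 0.703 with an estimated correlation). Of 12 neutrophil and mast cell markers 8 fell (8 fell and 1 rose adjusted over the list alone), with Mmp9 at −2.01 ± 0.32 (median −1.92, adjusted p = 0.0241, and adjusted p = 0.703 with an estimated correlation). Of 27 cell cycle genes, 11 fell, 1 rose and 15 did not pass, with Cdc20 at −2.60 ± 0.40 (median −0.82, adjusted p = 0.0258, 0.759 with an estimated correlation). Of 30 extracellular matrix genes 11 fell and 1 rose. The collagen genes Col1a2 fell by 2.37 ± 0.36 (GC-corrected −1.61) and Col1a1 by 2.64 ± 0.42 (GC-corrected −1.54); the list median was −0.63 (adjusted p = 0.0441, and adjusted p = 0.703 with an estimated correlation). The cell cycle call was lost without sWAT cold library 2 (adjusted p = 0.0861), cold library 3 (0.0602) or thermoneutral library 1 (0.0791), within 0.000204 to 0.759 over all alternatives. The matrix call was lost without the same libraries (0.0844, 0.0982 and 0.154) and with the GC correction (median −0.12, 0.310), within 0.0168 to 0.703. Skeletal muscle markers rose, 19 of 24 (20 adjusted over the list alone), with titin, Ttn, at 5.02 ± 0.84 and Neb at 5.19 ± 0.75 (median 3.89, adjusted p = 8.31e-06, and adjusted p = 0.700 with an estimated correlation).

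Splicing regulators moved both ways in sWAT and were not called as a list. Of 110 measured, 31 rose, 20 fell and 59 did not pass (median 0.09, adjusted p = 0.297), where 49.2% of all genes passed. With the GC correction 23 rose and 29 fell (median −0.14). Rbfox1 rose by 5.50 ± 0.58 (GC-corrected 4.92), Khdrbs3 by 4.06 ± 0.40 (2.97) and Mbnl2 by 2.69 ± 0.26 (2.73), with the share of muscle not told apart. Ptbp2 rose by 2.55 ± 0.28, with 0.31 and an adjusted p of 0.348 after the GC correction (5.30e-15 to 0.348 over all alternatives). Among genes past a mean log2 CPM of 3, the largest decreases in sWAT were those of Mir142hg (−5.19 ± 0.55), the host transcript of a microRNA of blood cells, Epb41l4aos (−4.30 ± 0.48), Ptpn18 (−4.02 ± 0.53), Dusp2 (−4.01 ± 0.28) and Basp1 (−3.96 ± 0.27).

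Of 16 beige and brown lineage markers 3 rose and 5 fell, with Epsti1 at −2.02 ± 0.34; the median was 0.21, the mean −0.13 and the direction of the test down (adjusted p = 0.766). Of 19 white adipocyte genes 6 rose, such as Pparg, the master regulator of adipocytes (2.33 ± 0.27), and 5 fell; the median was −0.22, the mean 0.03 and the direction of the test up (adjusted p = 0.766). Of 7 cold-inducible RNA-binding genes 2 rose and 1 fell; the median was −0.10, the mean 0.30 and the direction of the test up (adjusted p = 0.605). Of 19 clock genes 5 rose, such as Clock (2.78 ± 0.29), and 1 fell (median 0.26, adjusted p = 0.233). Of 19 secreted factors 8 rose and 5 fell (10 and 5 adjusted over the list alone; 0.76, 0.300), of 24 genes of the unfolded protein response 7 rose and 3 fell (5 and 2 adjusted over the list alone; 0.13, 0.734), and of 17 immediate early genes 1 rose and 3 fell (−0.25, 0.498). Endothelial markers rose in 5 and fell in 3 of 15, with the receptor gene Flt1 at 1.84 ± 0.24 (0.30, 0.592). In fibroblast markers 5 of 14 fell, with Clec3b at −3.17 ± 0.42 (−0.13, 0.177), and in Schwann and nerve markers 2 of 10 rose and 5 fell, with Cnp at −2.49 ± 0.24 (−0.38, 0.592). In smooth muscle markers 2 of 10 rose and 1 fell (0.24, 0.592), in eosinophil markers 3 of 7 fell (−1.49, 0.403), in lymphatic markers 1 of 7 fell and did not pass adjusted over the list alone (0.47, 0.766), in epithelial markers 4 of 5 fell (−1.65, 0.0742) and in erythrocyte markers 1 of 7 rose (0.46, 0.766). Of 3 thymus markers, too few for a list test, 0 passed in edgeR, DESeq2 or limma-voom, or at an unadjusted p under 0.05.

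In sWAT 7734 of 15731 genes passed, 3950 higher and 3784 lower in cold, and 3495 and 3209 of these changed at least 2-fold. With the GC correction 3811 were higher and 3028 lower, and 64.6% of the genes that had passed did so again in the same direction. Without sWAT cold library 1, which stood apart from the other cold libraries, 4224 were higher and 4495 lower. Camera called 17 of 33 lists, and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05; fry called 15.

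**Figure D4:**
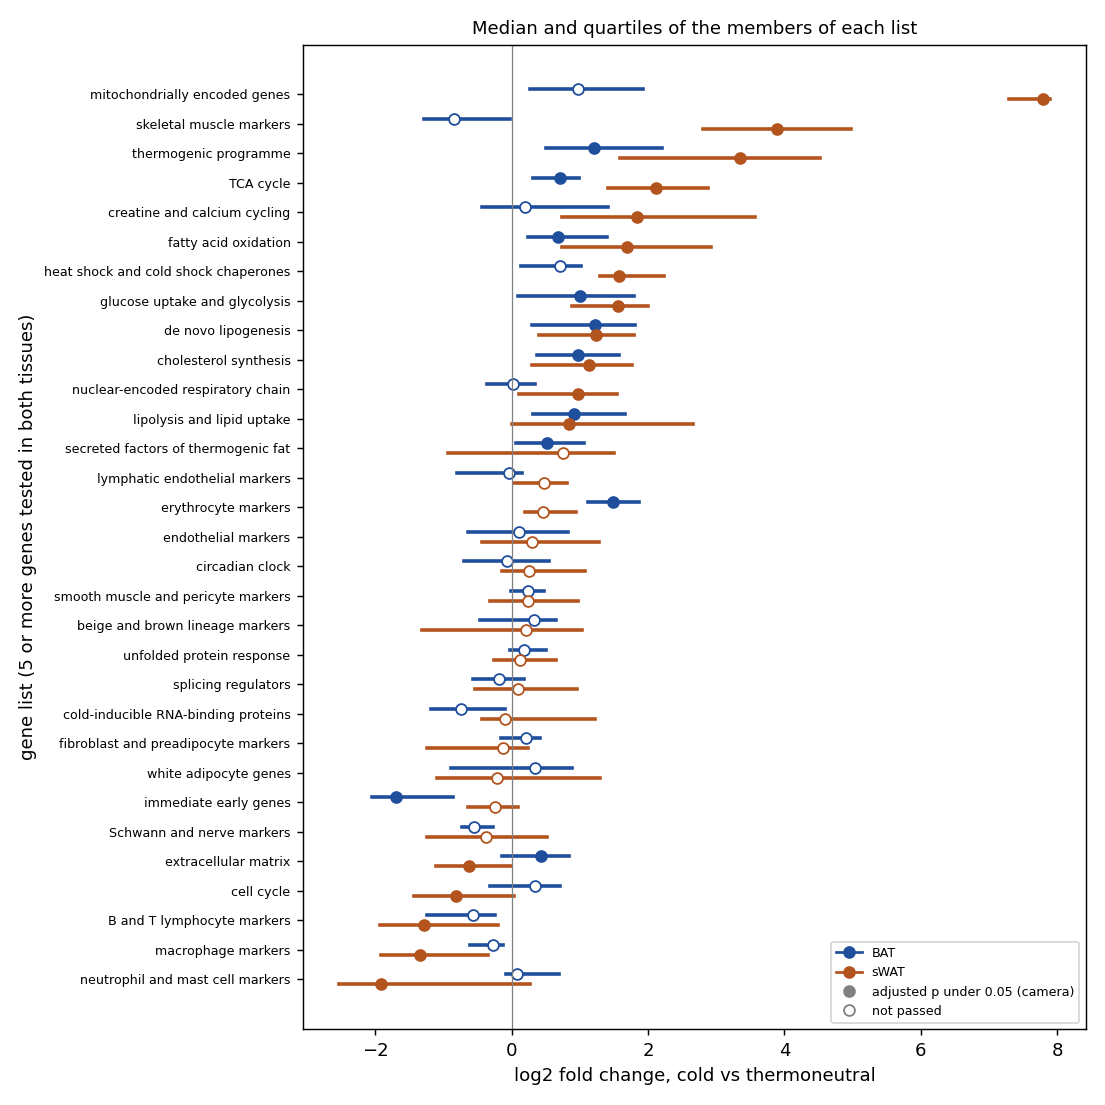
Median log2 fold change of the members of each gene list (points) with their quartiles (lines) for cold against thermoneutral BAT (blue) and sWAT (orange), for lists with at least 5 genes tested in both tissues; filled points have a camera adjusted p under 0.05. The mitochondrial genes have a median of 0.98 in BAT and 7.80 in sWAT, and the thermogenic programme of 1.20 and 3.36.

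The overlap of calls in BAT and sWAT was tested across genes as if they were independent, which they are not. Among 14219 genes tested in both tissues, 962 were higher in cold in BAT and 3904 in sWAT, and 561 were higher in both, against 264.1 expected of independent lists (Fisher's exact test, one-sided, p = 1.41e-96). For lower genes, 709 in BAT and 3069 in sWAT shared 231, against 153.0 expected (Fisher's exact test, one-sided, p = 2.17e-12). In opposite directions, 27 genes were higher in BAT and lower in sWAT, and 87 were lower in BAT and higher in sWAT. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.30 and a Spearman correlation of 0.27. Of the 10 splits of the 6 BAT libraries, 6, the real one included, gave a Spearman correlation with the sWAT change at least as large in size, up to 0.50 (with the GC correction 3, up to 0.46, where the real split gave 0.37), so the Fisher p does not measure chance between samples. With the GC correction 983 genes were higher in both (407.1 expected) and 444 lower in both (248.5 expected).

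The difference of responses is the change in sWAT minus that in BAT. A fall in BAT can make it positive, and a rise negative. Dio2 differed by 5.97 ± 0.65 (adjusted p = 0.000356), Ppargc1a by 3.61 ± 0.70 (0.00383) and Cidea by 3.00 ± 0.64 (0.00585). Lep differed by 2.71 ± 0.62 (0.00803), having fallen in BAT and not passed in sWAT. Ucp1 differed by 2.24 ± 0.98, which did not pass (adjusted p = 0.108), and passed without sWAT thermoneutral library 1 (3.48, 0.0159; 0.0159 to 0.234 over all alternatives). Elovl3 differed by 1.44 ± 0.73 (adjusted p = 0.159) and passed without sWAT cold library 1 (1.66, 0.0269; 0.0106 to 0.385). Cirbp differed by −1.33 ± 0.43 (adjusted p = 0.0382), with −0.65 and an adjusted p of 0.203 after the GC correction. Its call was also lost without BAT cold libraries 1 or 2 (0.0721 and 0.0668), BAT thermoneutral libraries 2 or 3 (0.0549 and 0.0574), sWAT cold libraries 2 or 3 (0.0541 and 0.0713) or sWAT thermoneutral library 1 (0.0971), within 0.00582 to 0.203. Rbm3 (1.41 ± 0.63, adjusted p = 0.116), Adipoq (1.13 ± 0.54, 0.137), Fasn (−0.79 ± 0.75, 0.454) did not pass.

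Some genes of mitochondria and muscle had a more positive change in sWAT, where a batch and muscle share are not told apart from a response. Counts adjusted over the list alone are given where they differ. All 13 mitochondrial genes had a more positive change, with mt-Nd6 at 7.93 ± 1.31 and mt-Cytb at 7.23 ± 0.82 (median 6.75, adjusted p = 4.77e-15, and adjusted p = 0.384 with an estimated correlation). Without BAT cold library 3 they differed by 8.63 and 7.92 (median 7.47), and mt-Nd6 by 7.16 without BAT thermoneutral library 2. Of 24 skeletal muscle markers 19 did (21 adjusted over the list alone), with Xirp2 at 7.11 ± 1.30 and Ttn at 6.11 ± 1.15 (median 4.32, adjusted p = 8.07e-09, and adjusted p = 0.746 with an estimated correlation). Of 27 thermogenic genes 11 had a more positive change in sWAT (12, and 1 the other way, adjusted over the list alone), with Esrrg at 3.07 ± 0.50 (median 1.44, adjusted p = 9.03e-04, and adjusted p = 0.746 with an estimated correlation). In the citric acid cycle 7 of 20 did (9 adjusted over the list alone), with Sucla2 at 3.76 ± 0.57 (median 1.41, adjusted p = 6.69e-04, and adjusted p = 0.746 with an estimated correlation). In the respiratory chain 13 of 55 did, with Uqcrb at 7.11 ± 0.48 (median 0.93, adjusted p = 0.00155, and adjusted p = 0.812 with an estimated correlation). This call was lost without BAT cold library 3 (adjusted p = 0.0580, 4.09e-08 to 0.812 over all alternatives). Of 16 heat shock genes 6 did (8 adjusted over the list alone), with Hspa1a at 5.53 ± 1.23 (median 1.27, adjusted p = 0.0155, and adjusted p = 0.746 with an estimated correlation). Of 17 immediate early genes 7 did (8 adjusted over the list alone), with Nr4a1 at 3.16 ± 0.51 and Nr4a3 at 2.47 ± 0.45 (median 1.35, adjusted p = 0.0166, and adjusted p = 0.746 with an estimated correlation). This call was lost without BAT cold library 3 (0.132) or sWAT thermoneutral library 3 (0.0591), within 3.83e-06 to 0.746.

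Some matrix, cell cycle, macrophage, neutrophil and mast cell genes had a more negative change in sWAT than in BAT. In the matrix 10 of 30 did (14, and 2 the other way, adjusted over the list alone), with Col1a1 at −3.11 ± 0.52 (median −1.14, adjusted p = 7.01e-05, and adjusted p = 0.746 with an estimated correlation). In the cell cycle 6 of 27 did, with Cdc20 at −3.39 ± 0.69 (median −0.85, adjusted p = 6.69e-04, and adjusted p = 0.746 with an estimated correlation). Of 19 macrophage markers 7 did and 2 had a more positive change, with C1qb at −1.85 ± 0.34 (median −0.67, adjusted p = 0.0142, and adjusted p = 0.746 with an estimated correlation). After the GC correction C1qb differed by −0.91 (adjusted p = 0.0845; 2.11e-07 to 0.0845 over all alternatives). Of 12 neutrophil and mast cell markers 6 did and 1 had a more positive change (median −2.30, adjusted p = 0.00155, and adjusted p = 0.746 with an estimated correlation). Of 14 fibroblast markers 4 did, with Pi16, a marker of fibroblast progenitors, at −2.25 ± 0.40 (median −0.31, adjusted p = 0.0305, and adjusted p = 0.746 with an estimated correlation). Of 20 lymphocyte markers 1 did, and 0 adjusted over the list alone (median −0.41, adjusted p = 0.104), and the list passed without BAT cold library 2 (0.0346), sWAT cold library 1 (0.000821) or sWAT thermoneutral library 2 (0.0295), within 0.000821 to 0.812. Of 7 eosinophil markers 0 passed in edgeR, 2 at an unadjusted p under 0.05, 1 in DESeq2 and 1 in limma-voom (median −1.05, adjusted p = 0.627). The macrophage call was lost without sWAT thermoneutral library 3 (adjusted p = 0.0827, 0.00163 to 0.746 over all alternatives). The fibroblast call was lost without BAT cold library 3 (0.0567), BAT thermoneutral library 2 (0.0692), sWAT cold library 3 (0.0509) or sWAT thermoneutral library 3 (0.0670) and with the GC correction (0.0604), within 0.00860 to 0.746. Of 111 splicing regulators, 27 had a more positive and 5 a more negative change in sWAT (27 and 6 adjusted over the list alone), with a median of 0.34 (adjusted p = 0.185), and 14 and 16 with the GC correction. Rbfox1 differed by 5.98 ± 0.87 (GC-corrected 5.29, muscle share not told apart) and Clk1 by 4.43 ± 0.67 (2.96).

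Between the responses, 4108 of 16365 genes differed, 2824 with a more positive and 1284 with a more negative change in sWAT, 2816 and 1255 by at least 2-fold. With the GC correction the counts were 2473 and 980, and 56.9% of the genes that had passed did so again in the same direction. Across genes, which are not independent replicates, the Spearman correlation of the difference with GC content was −0.55. The more positive count was 1485 without BAT cold library 1, 1497 without BAT cold library 2 and 1864 without BAT thermoneutral library 2. The more negative count was 2577 without BAT cold library 3, 1945 without sWAT cold library 1, 691 without sWAT cold library 3 and 830 without sWAT thermoneutral library 2. The share of more positive changes was 68.7%, and 58.4% with RLE scaling, 55.9% without the 10 most abundant genes, 56.1% with the DESeq2 Wald test and 59.7% without mitochondrial genes. The median of all genes was 0.12, and −0.03, −0.06, −0.01 and −0.01 under these. Camera called 12 lists, and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05; fry called 13.

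BAT against sWAT at thermoneutrality compares the depots when no extra heat is needed, and positive values are higher in BAT. A batch of the 3 sWAT libraries cannot be told apart from the depot here. Dio2 was higher by 6.96 ± 0.56 (adjusted p = 1.40e-06), Ppargc1a by 4.89 ± 0.57 (1.72e-05), Cidea by 4.00 ± 0.50 (2.92e-05), Ucp1 by 3.46 ± 0.75 (0.00160; 4.71 without sWAT thermoneutral library 1) and Elovl3 by 2.82 ± 0.55 (0.000790). Cirbp was lower in BAT (−2.62 ± 0.32, adjusted p = 2.48e-05). The B cell genes Cd79b (−7.61 ± 0.42, 0.688 ± 0.175 against 136 ± 12.2 CPM) and Cd79a (−7.62 ± 0.49) were among the lowest in BAT relative to sWAT, and mt-Nd6 (8.63 ± 1.15), mt-Cytb (8.32 ± 0.72) and mt-Atp6 (8.19 ± 1.15) highest. Lep (−0.51 ± 0.43, adjusted p = 0.319), Adipoq (0.55 ± 0.38, 0.225), Fasn (0.09 ± 0.53, 0.902) and Rbm3 (0.05 ± 0.44, 0.933) did not pass. With the GC correction Fasn passed (1.17, adjusted p = 0.0262; 0.0262 to 0.998 over all alternatives), as did Rbm3, lower in BAT (−1.24, 0.0102; 0.0102 to 0.997).

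Oxidative genes were higher in BAT at thermoneutrality, with counts equal when adjusted over the list alone except where given. All 13 mitochondrial genes were (median 7.66, GC-corrected 5.89; adjusted p = 3.27e-09, and adjusted p = 0.307 with an estimated correlation), as were 19 of 20 genes of the citric acid cycle, 1 being lower, with Sucla2 at 4.57 ± 0.45 (2.22; 1.13e-06, and adjusted p = 0.370 with an estimated correlation). Of 27 thermogenic genes 21 were higher and 1 lower (22 and 1 adjusted over the list alone), with Esrrg at 3.97 ± 0.39 (2.64; 8.34e-07, and adjusted p = 0.370 with an estimated correlation). In the respiratory chain 33 of 55 were higher and 1 lower, with Uqcrb at 7.51 ± 0.41 (1.43; 9.72e-06, and adjusted p = 0.511 with an estimated correlation). In fatty acid oxidation 18 of 26 were higher and 2 lower, with Decr1 at 3.68 ± 0.32 (1.46; 3.20e-04, and adjusted p = 0.448 with an estimated correlation). Of 16 heat shock genes 13 were higher, with Hsph1 at 3.17 ± 0.40 (2.13; 4.73e-05, and adjusted p = 0.307 with an estimated correlation). Of 24 muscle markers 18 were higher, with myoglobin, Mb, at 5.82 ± 1.03 (2.69; 2.35e-04, and adjusted p = 0.511 with an estimated correlation), beside muscle marker means of 8.07 to 270 CPM in the sWAT thermoneutral libraries.

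Immune and matrix genes were lower in BAT at thermoneutrality, with cell shares not told apart and counts equal over the list alone. All 20 lymphocyte markers were, with Lck at −6.99 ± 0.44 and Cd3d at −6.31 ± 0.43 (median −6.42, adjusted p = 2.19e-21, 0.307 with an estimated correlation). So were 16 of 19 macrophage markers, with C1qa at −3.37 ± 0.31 (−2.53; 5.14e-06, and adjusted p = 0.307 with an estimated correlation), and 21 of 27 cell cycle genes, with Mcm2 at −3.12 ± 0.34 (−2.05; 6.23e-06, and adjusted p = 0.376 with an estimated correlation). In the matrix 19 of 30 were lower and 4 higher, with Col1a1 at −3.72 ± 0.40 (−1.49; 0.00170, and adjusted p = 0.466 with an estimated correlation). Fibroblast markers were lower in 8 and higher in 1 of 14, with Pi16 at −3.87 ± 0.31 (−2.09; 0.00441, and adjusted p = 0.307 with an estimated correlation). Neutrophil and mast cell markers were lower in 9 and higher in 1 of 12, with Mmp9 at −3.46 ± 0.49 (−2.67; 0.00933, and adjusted p = 0.466 with an estimated correlation). Of 111 splicing regulators 42 were higher and 17 lower (median 0.32, adjusted p = 0.0567), and 32 and 31 with the GC correction. Khdrbs3 was higher by 4.13 ± 0.36 and Esrp2 by 5.67 ± 0.57, and Srpk3, a muscle kinase of splicing factors, was lower (−2.74 ± 0.29). The splicing list passed without BAT thermoneutral library 1 (adjusted p = 0.0379), BAT thermoneutral library 2 (0.0356) or sWAT thermoneutral library 2 (0.0485), within 0.00845 to 0.993 over all alternatives.

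At thermoneutrality 9599 of 16365 genes differed between the tissues, 4885 higher and 4714 lower in BAT, 4213 and 4103 by at least 2-fold. Across genes, which are not independent replicates, the Spearman correlation of fold change and GC content was −0.45. With the GC correction the counts were 4999 and 4450, and 74.3% of the genes that had passed did so again in the same direction. Camera called 19 lists, and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05; fry called 30. Of the 19 calls, 13 held without each single library. Beige and brown lineage markers (adjusted p = 0.0405) were lost without BAT thermoneutral library 1, 2 or 3 (0.0881, 0.0679 and 0.0550; 0.000178 to 0.307 over all alternatives), and endothelial markers (0.0292) without BAT thermoneutral library 1 (0.0979; 0.000372 to 0.511). Epithelial markers (0.0292) were lost without BAT thermoneutral library 3 (0.0516; 0.000247 to 0.376). Without sWAT thermoneutral library 3, glycolysis (0.0292 with all libraries) had 0.0758 (0.00189 to 0.511), immediate early genes (0.0373) 0.0758 (0.000247 to 0.307) and lipolysis (0.0292) 0.118 (0.00289 to 0.511).

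BAT against sWAT in cold shows how far the depots differ when both are stimulated. The genes of heat production named in every comparison did not pass. Ucp1 had 21898 ± 1603 CPM in BAT and 9342 ± 5370 in sWAT, a log2 fold change of 1.23 ± 0.69 (adjusted p = 0.290), with Dio2 at 1.00 ± 0.42 (0.155), Cidea at 0.99 ± 0.45 (0.179), Adipoq at −0.58 ± 0.38 (0.378), Fasn at 0.88 ± 0.53 (0.326) and Rbm3 at −1.36 ± 0.45 (0.0691), which passed with the GC correction (−1.35, 0.0221; 0.0166 to 0.445). Ppargc1a had 1.27 ± 0.49 (0.111) and Elovl3 1.38 ± 0.51 (0.101), and both passed without sWAT cold library 2 (1.93, 0.0337 and 1.92, 0.0435; 0.0337 to 0.229 and 0.0263 to 0.172 over all alternatives). Lep was lower in BAT (−3.23 ± 0.47, adjusted p = 0.000455, 10.8 ± 3.71 against 101 ± 66.6 CPM). Cirbp was lower (−1.29 ± 0.31, adjusted p = 0.0143), and did not pass without BAT cold library 2 (0.0675), BAT cold library 3 (0.0843) or sWAT cold library 1 (0.101), within 0.00254 to 0.101. Higher in BAT were Nr4a2, an immediate early nuclear receptor (1.84 ± 0.39, 52.8 ± 17.1 against 14.8 ± 5.09 CPM), and the vascular sialomucin gene Podxl (1.76 ± 0.33). Lower were the lymphatic chemokine gene Ccl21a (−7.00 ± 0.49) and the immunoglobulin genes Ighd (−6.68 ± 0.83) and Igkc (−6.03 ± 0.71). Without sWAT cold library 1 Lep had −2.34, Ighd −5.41 and Igkc −5.28.

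Markers of lymphocytes and macrophages were lower in BAT in cold, with cell shares not told apart. All 20 lymphocyte markers were (20 over the list alone), with Cd79b at −6.13 ± 0.40 and Cd3d at −5.93 ± 0.47 (median −6.28, adjusted p = 1.00e-57, 0.0636 with an estimated correlation). So were 12 of 19 macrophage markers (14 over the list alone), with Clec10a at −2.11 ± 0.30 (median −1.50, adjusted p = 1.11e-07, 0.268 with an estimated correlation). Of 12 neutrophil and mast cell markers 0 passed in edgeR, 3 at an unadjusted p under 0.05, 2 in DESeq2 and 0 in limma-voom (−0.57; 0.895). Cell cycle genes were lower in 7 of 27 (14 over the list alone, median −1.15, adjusted p = 5.62e-04, 0.390 with an estimated correlation). Beige and brown lineage markers, pooled across lineages, were lower in 9 and higher in 1 of 17 (9 and 2 over the list alone). Epsti1 had −4.78 ± 0.41 (list median −1.58, adjusted p = 0.00116, 0.268 with an estimated correlation). Of 14 fibroblast markers 7 were lower (8, and 2 higher, adjusted over the list alone), with Dpt, a matrix protein, at −2.27 ± 0.28 (−1.05; 0.0109, and adjusted p = 0.268 with an estimated correlation). This call was lost without sWAT cold library 2 (0.0540; 0.00281 to 0.268 over all alternatives). Endothelial markers were higher in 5 of 15 (5 adjusted over the list alone), with the receptor gene Kdr at 1.32 ± 0.30 (0.67; 7.74e-05, and adjusted p = 0.268 with an estimated correlation).

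The metabolic lists were called with few single genes past the threshold. Of 27 thermogenic genes 1 was higher, and 0 adjusted over the list alone (median 0.99, adjusted p = 6.82e-07, and adjusted p = 0.268 with an estimated correlation). In the citric acid cycle 1 of 20 was higher (0.74; 5.63e-05, and adjusted p = 0.310 with an estimated correlation), and in glycolysis 1 of 30 was higher and 2 lower, with Pfkp at 1.12 ± 0.28 and Eno2 at −2.45 ± 0.41 (0.60; 0.00248, and adjusted p = 0.386 with an estimated correlation). In fatty acid oxidation 0 of 26 passed in edgeR, 5 at an unadjusted p under 0.05, 3 in DESeq2 and 0 in limma-voom (0.56; 1.56e-04, and adjusted p = 0.312 with an estimated correlation). In cholesterol synthesis 0 of 22 passed in edgeR, 3 at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma-voom (0.32; 0.00740, and adjusted p = 0.224 with an estimated correlation). Of the 13 mitochondrial genes 0 passed in edgeR, 1 at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma-voom (1.09; 0.00810, and adjusted p = 0.442 with an estimated correlation). Of 111 splicing regulators 3 were higher and 3 lower (2 and 3 adjusted over the list alone), with Nova2, a neuronal splicing factor, at 1.13 ± 0.25 and Srpk3 at −2.11 ± 0.29. Their median was −0.07, their mean −0.11 and the direction of the test up (adjusted p = 0.308), and they passed without sWAT cold library 1 (0.0381, to 0.762 over all alternatives). The mitochondrial call was lost without BAT cold library 3 (adjusted p = 0.428) or sWAT cold library 2 (0.0553), within 0.000385 to 0.442 over all alternatives, and glycolysis without sWAT cold library 1 (0.0554; 0.000174 to 0.386).

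In cold 2015 of 16365 genes differed between the tissues, 195 higher and 1820 lower in BAT, 122 and 1792 by at least 2-fold, and 461 and 2251 with the GC correction. The higher count was 327 without BAT cold library 3, and 100, 443 and 47 without sWAT cold libraries 1, 2 and 3. The lower count was 1040 without BAT cold library 1, 977 without BAT cold library 2 and 1000 without sWAT cold library 1. The share higher in BAT was 9.68%, and 25.8% without the 10 most abundant genes and 24.9% with the DESeq2 Wald test, where the first moved the median of all genes from −0.03 to 0.13. Camera called 21 of 33 lists, and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05; fry called 13. Of the 21 calls 14 held without each single library. The losses not given above were de novo lipogenesis (median 0.41, adjusted p = 0.0224) without BAT cold library 1 (0.0526) or sWAT cold library 3 (0.0524; 0.00623 to 0.413 over all alternatives), and lymphatic markers (−0.92, 0.0231) without BAT cold library 1 (0.0605; 0.00607 to 0.268). Without sWAT cold library 1, lipolysis (0.40, 0.0110) had 0.0698 (0.00293 to 0.425) and the nuclear respiratory chain (0.41, 0.000562) 0.282 (6.12e-07 to 0.572). The other calls were those of heat shock genes (0.75), erythrocyte (1.18), smooth muscle (0.67), eosinophil (−2.30) and epithelial markers (−2.27).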

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

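The tests of fewer mitochondria, of mitochondrial RNA removed in a batch, of a lower share of lymphocytes and of a batch in sWAT were chosen after the results were seen. The values of genes and lists that follow are differences of the response to cold, sWAT minus BAT, on the log2 scale. They are listed since the interaction term of the model passed for each, except for the list medians, which stand for lists called by camera with a preset correlation, 0 of which passed with an estimated correlation, where 2 had an unadjusted p under 0.05 and fry called 13.

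In all, 2824 genes had a more positive and 1284 a more negative change in sWAT than in BAT. Of 100 drawn splits of the libraries within each tissue, out of 200 possible, 5 gave at least as many genes as the real 4108, itself included. The highest other gave 7119. All 5 keep the sWAT groups whole, 10 of the drawn splits do so, and the 90 that mix them gave at most 342. Splits that keep the sWAT groups whole hold the sWAT difference, so their number does not decide whether chance is excluded and points to the structure of the sWAT samples. For the other comparisons the 10 splits of 6 libraries are too few for a share under 0.05. By edgeR's quasi-likelihood test the real splits gave 1777 genes in BAT, 7734 in sWAT, 9599 between tissues at thermoneutrality and 2015 in cold. The others gave 0. At an unadjusted p under 0.05 they gave up to 1071, 618, 716 and 2868, against 4271, 8916, 10363 and 4212 for the real ones. Mixed splits hold the group difference in their spread, so these counts are no false-call rate.

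Among genes of heat production and signalling the differences were 5.97 for Dio2, 3.61 for Ppargc1a, 3.00 for Cidea, 2.71 for Lep, 3.07 for Esrrg and −1.33 for Cirbp, with a median of 1.44 for the thermogenic programme. Mitochondrial genes differed by 7.93 (mt-Nd6), 7.23 (mt-Cytb) and 7.02 (mt-Nd4), with a median of 6.75. Nuclear respiratory chain genes had a median of 0.93, with Uqcrb at 7.11 and Ndufs1 at 2.79, and the citric acid cycle 1.41, with Sucla2 at 3.76 and Dld at 3.57. Skeletal muscle markers had a median of 4.32, with Xirp2 at 7.11 and Ttn at 6.11, and Myl2 differed by 7.83 and Trdn by 7.82. Heat shock genes had a median of 1.27, with Hspa1a at 5.53 and Dnaja1 at 2.07, and immediate early genes 1.35, with Nr4a1 at 3.16 and Nr4a3 at 2.47.

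Among genes with a mean log2 CPM of at least 3, the most negative differences were those of Loxl1 (−4.21), E2f2 (−3.70) and Marc1 (−3.68). Extracellular matrix genes had a median of −1.14, with Col1a1 at −3.11 and Eln at −2.71, and cell cycle genes −0.85, with Cdc20 at −3.39 and Mcm2 at −1.98. Fibroblast markers had a median of −0.31, with Pi16 at −2.25 and Icam1 at −2.20, and macrophage markers −0.67, with C1qb at −1.85 and C1qa at −1.71. Neutrophil and mast cell markers had a median of −2.30; Camp (−8.17) and Ngp (−6.54) rest on near 0 counts, with means of 0.0598 and 0.0868 CPM in cold sWAT. The differences of Cirbp, Dnaja1, Eln, C1qb and C1qa did not pass with the GC correction.

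Mitochondrial RNA was far lower in the 3 sWAT thermoneutral libraries, with a median log2 change of 7.80 (SD 0.47 across the 13 genes) from thermoneutral to cold. A GC trend is excluded as the whole cause, since 1326 nuclear genes of the same GC content had a median of 1.52 (SD 1.73). Fewer mitochondria stay open, as nuclear respiratory chain genes (55, median 0.97, SD 1.56) do not measure them. The removal of mitochondrial RNA or reads in a batch of libraries may account for it, since the 13 genes moved by a like factor (SD 0.47) and the lowest share in another library was 57.4 times the highest in these. As the 3 libraries are also all of their group, such a batch cannot be told apart from the temperature, and a biological change of mitochondrial RNA stays open.

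In sWAT 7734 genes passed between cold and thermoneutral libraries that differ in their GC trend. The trend is excluded as the whole cause, since 64.6% of the calls were kept in the same direction after the GC correction, and it stays open for the calls that were not kept. Fewer lymphocytes in cold, which would raise adipocyte genes alike, are not the whole cause. The thermogenic median lay 3.58 (SE 0.77 across genes) above the white adipocyte one. A response of the tissue to cold, the share of muscle and a batch of the 3 thermoneutral libraries cannot be told apart and stay open. The GC-corrected sWAT and BAT responses had a Spearman correlation of 0.37 across genes. Other splits of the BAT libraries gave up to 0.46 in size.

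Cirbp, which encodes an RNA-binding protein known to be induced when cells cool, was lower in cold, with a fall that passed in sWAT and did not pass in BAT (adjusted p = 0.101). At its GC content of 53.7%, a GC trend is excluded as the whole cause in sWAT, since the GC-corrected change was −1.73 (SE 0.27, adjusted p = 0.00194, within 1.40e-09 to 0.00530 over all alternatives). In BAT the corrected change was −1.03 (SE 0.24, adjusted p = 0.0197, within 0.0197 to 0.211). A response to the temperature of the animals remains open and was not tested by other means.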

How the results depend on the processing

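The GC correction, the totals without mitochondrial genes and the fits without both BAT libraries numbered 3, with or without sWAT cold library 1, were chosen after seeing the data. For each value that follows the cause was not tested, except where the choice itself gives fewer genes or samples. In BAT 996 genes were higher and 781 lower in cold. The higher count became 1540 with the DESeq2 Wald test, 1576 with the GC correction and 3265 without both BAT libraries numbered 3, and the lower count 1216 in a fit over all 12 libraries, 1521 with the GC correction and 3244 without both libraries numbered 3. Of the difference of responses, the lower count of 1284 became 2286 with the DESeq2 Wald test and 2448 without both BAT libraries numbered 3 and sWAT cold library 1. Between the tissues in cold, the higher count of 195 became 298 with RLE factors, 549 without the 10 most abundant genes, 681 with the DESeq2 Wald test, 461 with the GC correction, 320 without mitochondrial genes, 116 in a fit of the 6 libraries compared and 122 with a minimum 2-fold change, which only removes genes. The overlap of higher genes went from 561 to 983 with the GC correction, and that of lower genes from 231 to 444 with it and to 487 in a fit over all 12 libraries. fry called 30 lists in place of 19 between the tissues at thermoneutrality and 13 in place of 21 in cold.

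Leaving out each library in turn gave 303 (without BAT thermoneutral library 2) to 1378 (without BAT cold library 3) higher and 146 (without BAT cold library 2) to 1105 (without BAT cold library 3) lower genes in BAT. For the difference of responses it gave 1485 (without BAT cold library 1) to 2921 and 691 (without sWAT cold library 3) to 2577 (without BAT cold library 3), and between the tissues in cold 47 (without sWAT cold library 3) to 443 (without sWAT cold library 2) and 977 (without BAT cold library 2) to 1686. The counts in sWAT (3068 to 4224 and 2604 to 4495) and between the tissues at thermoneutrality (4311 to 4689 and 4225 to 4617) moved by less than 1.5 times. Of the named genes past the threshold, 43 of 83 kept their calls without each library in BAT, 123 of 132 in sWAT, 86 of 114 in the difference of responses, 134 of 138 between the tissues at thermoneutrality and 41 of 72 in cold. The fold of 7, 15, 41, 23 and 23 of them moved by over 1.5 times without 1 of the libraries, which is not given beside each gene.

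Of named genes, 2 reversed, both with the GC correction. Chordc1 in sWAT went from 1.76 to −0.21 (adjusted p = 0.490, within 1.22e-06 to 0.490), and Rbm3 between the tissues at thermoneutrality from 0.05 to −1.24. Left-out libraries aside, alternatives kept direction and side of the threshold of named genes in 1304 of 1383 BAT and 1755 of 1777 sWAT results. For the difference of responses it was 1746 of 1845, where the GC correction kept 94 and lost 30 and robust=FALSE kept 124. Between the tissues it was 2243 of 2265 at thermoneutrality and 1370 of 1478 in cold.

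Whether the experiment numbers of the libraries mark a shared block is not stated, and residuals leave it open. Of 18 pairs of libraries with the same number, 8 had residuals correlated above 0.1 (range −0.47 to 0.53), and the library with the same number was the best match in 14 of 36 cases. Between cold and thermoneutral BAT the 3 pairs had 0.306, 0.0665 and 0.289. With a block for the library number 1493 genes were higher and 1306 lower in BAT and 3302 and 3207 in sWAT, and with a block within temperature 107 were higher in BAT than in sWAT in cold. A block within temperature could not be fitted in a single tissue, where it leaves no residual degrees of freedom.

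Simulations with 69 or 70 genes changed by a log2 of 1 recovered at most 8.70% (0% for the difference of responses). Recovery with more changed was not tested. A gene that did not pass is not shown equal.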

Other observations

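Single genes of immune cells and vessels differed between the depots, where the share of lymphoid tissue is not told apart. Ccl21a, a chemokine of lymphatic vessels, was lower in BAT (log2 −6.96 ± 0.48 at thermoneutrality, −7.00 ± 0.49 in cold). Of 7 lymphatic markers 2 were higher and 2 lower at thermoneutrality, and 1 and 1 in cold. Gata3, a regulator of type 2 immune cells, was lower in BAT at thermoneutrality (−4.46 ± 0.57), and Tpsb2, a mast cell tryptase, by −4.42 ± 0.55, while Kit, the receptor of mast cells, was higher (1.72 ± 0.28).

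The balance between mitochondrial genes differed in BAT thermoneutral library 3. Before scaling it had 69750 CPM of mt-Cytb and 26129 of mt-Nd5, against 33516 and 38456 of mt-Cytb and 4160 and 5640 of mt-Nd5 in thermoneutral libraries 1 and 2. It had 3943 CPM of mt-Atp6, against 48526 and 48827, and 780 CPM of mt-Co3, against 50240 and 43928.

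In sWAT cold library 1, Elovl3 was at 111 CPM and Ucp1 at 3211 CPM, against 608 and 554 CPM of Elovl3 and 13212 and 11603 CPM of Ucp1 in cold libraries 2 and 3.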
